A study of Mus musculus with 4 samples.

How the data were processed

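Whole lung was collected from 4 female MMTV-PyMT mice on the FVB/NJ background, which carry the polyoma middle T oncogene as a mammary tumour transgene. The mice were 13 weeks old and had carried a pellet from 8 weeks of age, for 5 weeks. The pellet of 2 mice was a placebo, and that of 2 mice held 5 mg tamoxifen with release over 60 days. Per the labels, perfused lungs were digested to single cells, and each mouse gave 1 library of 10x Genomics 5' gene expression. The mouse is the replicate, and cells were never counted as replicates.

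The deposited matrices hold raw UMI counts per gene and barcode for 32285 genes, and their headers name Cell Ranger 5.0.0. The submitters' processing notes name Cell Ranger 8.0.1 and the mm10 build, and which version made the matrices was not settled. The deposited barcodes numbered 9776 and 7272 in the placebo mice and 7539 and 10168 in the tamoxifen mice, and the smallest UMI count of a barcode was 500 in each library.

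Cells with at least 250 genes and at most 15% mitochondrial UMIs were kept. In the placebo mice 2110 and 501 barcodes had fewer genes, and in the tamoxifen mice 525 and 2573. Of these barcodes, 97.8% and 83.0% in the placebo mice and 92.2% and 94.7% in the tamoxifen mice had over 50% of their UMIs from haemoglobin genes. Doublets were scored with Scrublet as run by scanpy 1.11.5. Its automatic threshold marked 1 and 0 cells in the placebo mice and 151 and 2 in the tamoxifen mice and was taken as failed, so a fixed score threshold of 0.25 was set after that was seen. It removed 2.71% and 1.57% of the placebo cells and 2.80% and 1.94% of the tamoxifen cells. There remained 7433 and 6651 placebo cells and 6804 and 7420 tamoxifen cells, with median UMI counts of 2616 and 4058 and of 3227.5 and 2900.5.

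Cells of all mice were clustered together from 2000 variable genes and 40 principal components with the Leiden method of leidenalg 0.10.2 at resolution 4, which gave 89 clusters. Marker genes for 36 cell types and states were fixed before the data were examined. By rule, 69 clusters took the name of the marker list with the highest score, which gave 29 classes, and the others stayed unnamed because of doublets, haemoglobin with another class, signs of another class, cycling genes or too few own markers. The 20 unnamed clusters held 6.13% and 3.28% of the placebo cells and 3.66% and 7.05% of the tamoxifen cells. A class is named with "-like" because it rests on marker genes alone. The resolution and the naming thresholds were set after the clusters and their cells per mouse had been seen and before any test between the groups.

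The place of cluster 47, led by Retnla, Fcna, Prg4 and Alox15, was decided more than once. By rule, a cluster with a best score under 2.0 stayed unnamed if its score for another class was over 0.7. Cycling and classes related to the best one did not count there, such as the T and innate lymphoid cells or the endothelial classes among themselves. Cluster 47 scored 1.65 for interstitial macrophage and 0.7 for classical monocyte, which was not over the threshold, so it stayed in the interstitial macrophage class. With its cells per mouse known, it was then set apart by a rule that named its genes, and the tests between the groups were first run in that form. That version gave 0 calls in the interstitial macrophage class, and the general capillary endothelial class, with 4 calls, tied as one more main class. The placement by the general rule was then restored, because the other had been made for this cluster, and the class without cluster 47 is given as an alternative.

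UMI counts were summed per mouse and class and tested with edgeR 4.0.16 under R 4.3.3, with TMM scaling, the filterByExpr count filter and the quasi-likelihood F test. Adjustment was by Benjamini-Hochberg within a class, with 0.05 as the threshold. The 21 classes with at least 20 cells in each mouse were tested, and the 8 whose smallest mouse held the most cells were the main classes. Differences are tamoxifen over placebo, CPM stands for TMM-scaled UMI counts scaled to a common total, and the standard error (SE) of a log2 fold change was derived from the F statistic.

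Shares of cells were tested with the edgeR F test on cells per class, with the kept cells of a mouse as its total, for classes and unnamed clusters with a mean of at least 10 cells. Clusters left unnamed for doublets or haemoglobin were not tested, a choice made after the clusters were seen. A two-sided exact permutation test of the shares was run beside it. The 34 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, where at least 5 members were measured, and again with an estimated correlation and with fry. Of the lists, 33 were written out before the data were examined, and the list of ribosomal proteins took each symbol that starts with Rpl or Rps, with some pseudogenes and a few genes of other function among them. Other classes than the main ones were tested for single genes only, and DESeq2 1.42.0 was run on the main classes as another test.

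The genes named in the main classes follow a rule fixed before the data were examined. In a class with fewer than 6 calls all calls are named. For the lists described in a class and for the oestrogen response list, the members with the smallest p are named, 2 for each list, of which some are printed. Esr1, Pgr and Greb1 are given for every main class. Receptor segments of B and T cells were to be counted without a name, and Igkv12-98 and Trbv20 were named after their values were seen, as were all genes of the other classes. Positions are from GENCODE release 21 for mouse, matched by gene identifier.

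The expression test was tested on simulated counts with 200 changed genes per main class, drawn with the means, library sizes and dispersions of the data. Of 100 genes changed 4-fold it recovered from 80 in the non-classical monocyte class to 95 in the neutrophil class. Of 100 genes changed 2-fold it recovered from 18 to 60 in the same classes. With 200 genes changed, the adjusted threshold was easier to reach than in the data, where a main class had at most 5 calls. These figures therefore do not say that a 4-fold change would have been called in the data. Ccnb2 in the alveolar macrophage class, for example, was not called at a log2 fold change of -2.71. The share of false calls exceeded the nominal 5% in 6 of the 8 main classes. Of the calls, 27 of 141 were false in the alveolar fibroblast class, 18 of 146 in the B cell class, 21 of 176 in the neutrophil class, 17 of 143 in the interstitial macrophage class, 15 of 160 in the alveolar macrophage class and 11 of 143 in the CD8 T cell class. The other two, the CD4 T cell and non-classical monocyte classes, had 5 of 123 and 2 of 100.

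The alternatives were other size factors, DESeq2, no count filter, the replicate number as a block, each mouse left out, doublets kept, at least 500 genes and at most 8% mitochondrial UMIs per cell, each cell assigned on its own by its markers, equal cells per mouse, and leaving out genes under 5% of their level in their highest class. For shares they also included TMM factors over classes and shares within immune or other cells. Binomial intervals are exact Clopper-Pearson intervals at 95%, and a count of 0 is given a limit of 3 counts. Both cover counting error only.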

Results

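Lungs of 2 placebo and 2 tamoxifen mice that carry the PyMT mammary tumour transgene were profiled by single-cell RNA sequencing, to compare lung cells after long exposure to tamoxifen with those after placebo. The libraries held 32728083 and 37285982 UMIs in the placebo mice and 32646505 and 35625624 in the tamoxifen mice. The main classes were neutrophil-like (11755 cells), CD4 T cell-like (2235), B cell-like (1795), alveolar macrophage-like (1203), alveolar fibroblast-like (1160), non-classical monocyte-like (923), interstitial macrophage-like (889) and CD8 T cell-like cells (885).

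The first comparison was of the make-up of the lung. Mesothelial-like cells, which line the lung surface, made up 0.867 ± 0.334% of placebo cells and 2.56 ± 0.738% of tamoxifen cells (SD, n = 2), a log2 difference of 1.56 ± 0.60 (SE). Cluster 30, the largest of this class, held 73 and 35 placebo cells and 71 and 149 tamoxifen cells. The others lay in clusters 65 and 72, found mostly in the tamoxifen mice, and the share without these was not tested. Platelet or megakaryocyte-like cells were at 0.395 ± 0.0694% and 0.869 ± 0.315% (SD, n = 2). Aerocyte endothelial-like cells, the capillary cells of gas exchange, were at 0.916 ± 0.00164% and 0.515 ± 0.0614%, and alveolar fibroblast-like cells at 4.85 ± 1.12% and 3.31 ± 0.106% (SD, n = 2). Cluster 51, with a median of 675 UMIs per cell, gave 80 of the 270 alveolar fibroblast-like cells of placebo 2. It gave 19 in placebo 1 and 22 and 18 in the tamoxifen mice, and the share without it was not tested. None of the 34 classes and clusters passed the edgeR test, where 1, the mesothelial-like share, had an unadjusted p under 0.05 and an adjusted p of 0.939. In 9 of the 34, these 4 among them, both tamoxifen mice lay outside both placebo mice, which chance gives in 33.3%, and their exact two-sided permutation p was 0.333, the smallest that 2 mice against 2 allow. The share of club or secretory-like cells was tested among the 34 but is not read as a comparison, since Bpifa1, a marker by which they were named, differed between the groups.

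Neutrophil-like cells made up 32.3% of cells (95% Clopper-Pearson interval 31.2 to 33.3%) in placebo 1 and 58.3% (57.1 to 59.5%) in placebo 2, and 35.8% (34.6 to 36.9%) and 41.1% (39.9 to 42.2%) in the tamoxifen mice. The B cell-like share, 7.64% and 1.92% in the placebo mice, was 4.78 ± 4.04% with placebo and 7.91 ± 5.84% with tamoxifen (SD, n = 2). Neither passed the edgeR test, with an adjusted p of 0.939 for each. The log2 difference of the B cell-like share was 0.72 with all mice and -0.34 without tamoxifen 1. That of the neutrophil-like share was -0.24 with all mice and 0.25 without placebo 2.

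**Figure D1:**
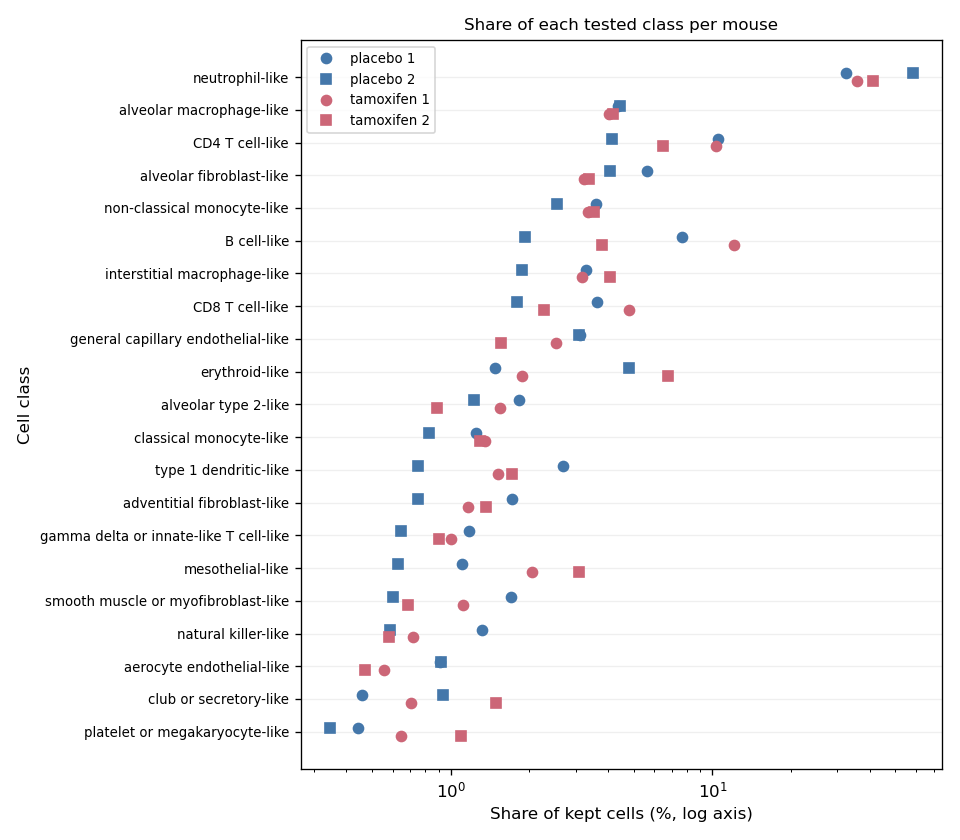
Share of kept cells (percent, log axis) in each of the 21 tested classes, with 1 point per mouse, blue for placebo and red for tamoxifen, and circles and squares for replicates 1 and 2. The neutrophil-like share ran from 32.3% to 58.3% within the placebo group, and the mesothelial-like shares of both tamoxifen mice lay above those of both placebo mice.

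The second comparison was of expression within a class. In CD8 T cell-like cells the haemoglobin genes Hbb-bs, Hba-a1 and Hbb-bt fell with tamoxifen, as did Ier3, an immediate early gene, and the T cell receptor segment Trbv20 rose. Hbb-bs went from 3102 ± 814 to 982 ± 41.0 CPM (SD, n = 2), a log2 fold change of -1.66 ± 0.19 (SE) with an edgeR adjusted p of 0.000353. Hba-a1 went from 1695 ± 186 to 651 ± 44.6 CPM, Hbb-bt from 234 ± 64.8 to 92.9 ± 11.0 CPM, Ier3 from 76.7 ± 27.7 to 20.8 ± 4.36 CPM and Trbv20 from 4.85 ± 6.86 to 57.2 ± 0.955 CPM (SD, n = 2). In these cells the haemoglobin genes lay at 0.400% to 0.566% of their level in erythroid-like cells, and Ier3 at 0.913% of its level in basophil or mast-like cells. With equal cells per mouse none of the 5 passed, with an adjusted p of 0.995 for each and log2 fold changes of -0.94 for Hbb-bs, -0.86 for Hba-a1, -0.76 for Hbb-bt, -1.36 for Ier3 and 2.63 for Trbv20. With cells assigned singly none passed either, with log2 fold changes of -1.34 for Hbb-bs, -0.21 for Hba-a1, -2.00 for Hbb-bt, -1.23 for Ier3 and 2.20 for Trbv20. DESeq2 did not call Ier3 (log2 fold change -1.84, adjusted p 0.387) or Trbv20 (3.47, adjusted p 1.00), and Ier3 was also lost with doublets kept, at a log2 fold change of -0.96. Trbv20 had 8 and 0 UMIs in the placebo mice, and its log2 fold change was 3.23 with all mice and 8.43 without placebo 1, a value that has no UMI behind it in the placebo group and is no measured fold.

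Cd74, the invariant chain of MHC class II, rose in CD4 T cell-like cells from 28.6 ± 11.6 to 94.8 ± 13.3 CPM (SD, n = 2), a log2 fold change of 1.65 ± 0.22 (SE) with an edgeR adjusted p of 0.0110. It lay there at 0.139% of its level in type 1 dendritic-like cells. Without tamoxifen 1 the log2 fold change was 1.49 with an adjusted p of 0.124. With doublets kept, with cells assigned singly and with equal cells per mouse it was 0.59, 1.28 and 2.22, with adjusted p of 1.00, 1.00 and 0.412. In B cell-like cells the immunoglobulin light chain segment Igkv12-98 had 0 UMIs in both placebo mice and 336 and 72 in the tamoxifen mice, at least 62.3-fold higher against a limit of 3 counts over the placebo group. This limit was 18.7-fold without placebo 1, 43.6-fold without placebo 2, 37.8-fold without tamoxifen 1 and 72.3-fold without tamoxifen 2. Its edgeR adjusted p was 0.00856, and 0.0898 with cells assigned singly, where its log2 fold change was no smaller.

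Marco, a scavenger receptor of macrophages, rose in interstitial macrophage-like cells from 47.4 ± 11.1 to 204 ± 9.69 CPM (SD, n = 2), a log2 fold change of 2.09 ± 0.19 (SE) with an edgeR adjusted p of 0.0274. Of its 1039 UMIs in the class, 3 lay outside cluster 47, led by Retnla, Fcna, Prg4 and Alox15, which held 40 and 9 cells of the placebo mice and 76 and 69 of the tamoxifen mice. Without cluster 47 Marco was too low to test and no gene of the class was called, and without the count filter its adjusted p was 0.865 at a log2 fold change of 2.11. The call therefore stands for the class with that cluster in it and not for the other interstitial macrophage-like cells.

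No gene passed in neutrophil, alveolar macrophage, alveolar fibroblast or non-classical monocyte-like cells. There edgeR gave 229, 280, 271 and 168 genes at an unadjusted p under 0.05, and DESeq2 called 1, 0, 0 and 0. The edgeR counts were 2.67%, 4.65%, 2.64% and 2.46% of the tested genes, all under the 5% that chance gives. The 0 edgeR calls became 157, 42, 97 and 30 calls without placebo 1 and 67, 36, 11 and 40 without placebo 2. Without tamoxifen 1 non-classical monocyte-like cells had 9 calls, and without tamoxifen 2 they had 10 and alveolar fibroblast-like cells 16.

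**Figure D2:**
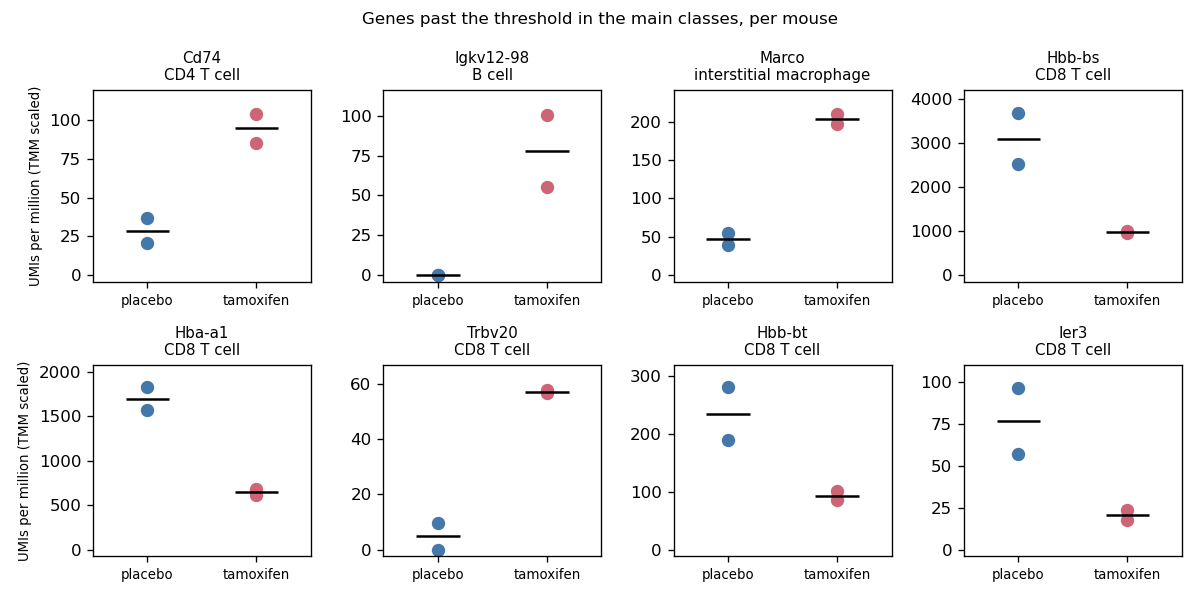
TMM-scaled UMI counts per mouse (linear axes) for the 8 genes past the threshold in the main classes, with 1 point per mouse, blue for placebo and red for tamoxifen, and a line at the group mean. In CD8 T cell-like cells Hbb-bs lay at 3678 and 2527 CPM in the placebo mice and at 953 and 1011 CPM in the tamoxifen mice.

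The called genes were placed on the mm10 build. Hbb-bs (ENSMUSG00000052305) spans 103826534 to 103828096 and Hbb-bt (ENSMUSG00000073940) 103812524 to 103813996 on chromosome 7, and Hba-a1 (ENSMUSG00000069919) spans 32283511 to 32284465 on chromosome 11. Trbv20 (ENSMUSG00000076476) spans 41188273 to 41188977 and Igkv12-98 (ENSMUSG00000076526) spans 68570763 to 68571235 on chromosome 6. Ier3 (ENSMUSG00000003541) spans 35821684 to 35822923 on chromosome 17, Cd74 (ENSMUSG00000024610) spans 60803848 to 60812652 on chromosome 18 and Marco (ENSMUSG00000026390) spans 120474538 to 120505024 on chromosome 1.

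Gene lists were called 57 times in 242 tests by camera. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.273, or with fry, where it was 0.218. With 2 mice per group the estimate leaves few degrees of freedom, so a call could hardly pass and its loss decides little. The preset correlation was not taken from these mice, so the calls made with it carry little weight either. In alveolar macrophage-like cells the proliferation list was lower, with a median log2 fold change of -0.91 over 18 genes, an adjusted p of 1.23e-19 by camera and adjusted p = 0.273 with an estimated correlation. None of its members passed over all genes, and 9 were lower adjusted over the list alone. Ube2c, which acts at the exit from mitosis, was at 80.1 ± 6.59 and 27.0 ± 9.22 CPM, and the cyclin gene Ccnb2 at 25.9 ± 9.04 and 3.76 ± 0.863 CPM (SD, n = 2). Cluster 73 of this class, with Birc5 among its leading genes and a score of 2.46 for cycling genes, held 25 and 21 placebo cells and 12 and 7 tamoxifen cells. Without it 7 genes of the list could be tested, with a median log2 fold change of -0.26 and an adjusted p of 0.119 by camera, and Ube2c and Ccnb2 were too low to test. The NF-kB inflammatory response list was higher there, with an adjusted p of 3.87e-05 by camera and adjusted p = 0.585 with an estimated correlation. Its cytokine genes Tnf and Il1b were at 96.5 ± 21.5 and 180 ± 12.1 CPM and at 308 ± 20.5 and 465 ± 118 CPM (SD, n = 2), none passed, and 1 member was higher adjusted over the list alone. With cells assigned singly Il1b went the other way, at a log2 fold change of -0.65.

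In interstitial macrophage-like cells the same NF-kB list was higher, with an adjusted p of 1.32e-05 by camera and adjusted p = 0.705 with an estimated correlation. Il6, an inflammatory cytokine, was at 10.7 ± 4.64 and 48.9 ± 6.48 CPM (SD, n = 2) and did not pass, with an edgeR adjusted p of 0.0996. It was the only member higher adjusted over the list alone. Without cluster 47 the list had an adjusted p of 0.00337 by camera, Il6 had a log2 fold change of 1.43 with an adjusted p of 1.00, and 0 members were higher adjusted over the list alone. In CD4 and CD8 T cell-like cells the same list was lower, with adjusted p of 0.0140 and 0.00520 by camera and adjusted p = 0.625 and 0.651 with an estimated correlation. Adjusted over the list alone, 1 and 4 of its members were lower there, and 1 was higher in the CD8 T cell-like cells. Il1b, Cxcl2 and Nfkbia of this list were highest in neutrophil-like cells. Leaving out genes under 5% of their highest class lowered the number of list calls in both T cell-like classes. RNA or cells of other classes were not tested as a source of these list differences.

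MHC class II genes, which present antigen to CD4 T cells, were higher as a list in non-classical monocyte, CD4 T cell and alveolar fibroblast-like cells. In non-classical monocyte-like cells the median log2 fold change was 0.77 over 9 genes, with an adjusted p of 4.75e-14 by camera and adjusted p = 0.747 with an estimated correlation. H2-Aa was at 645 ± 323 and 1610 ± 72.3 CPM and H2-Ab1 at 424 ± 129 and 877 ± 61.0 CPM (SD, n = 2), none passed over all genes, and 4 were higher adjusted over the list alone. In CD4 T cell-like cells the adjusted p was 4.62e-11 by camera and adjusted p = 0.625 with an estimated correlation, with Cd74 the only member of 6 past the threshold and 3 higher adjusted over the list alone. In alveolar fibroblast-like cells it was 0.000327 by camera and adjusted p = 0.818 with an estimated correlation, and 0 members were higher adjusted over the list alone.

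In neutrophil-like cells with all clusters the granule list was lower, with a median log2 fold change of -0.25 over 15 genes, an adjusted p of 2.59e-05 by camera and adjusted p = 0.804 with an estimated correlation. Camp, an antimicrobial peptide gene of granules, was at 743 ± 159 and 277 ± 59.9 CPM and Chil3 at 79.2 ± 50.1 and 15.2 ± 0.107 CPM (SD, n = 2). None passed over all genes, and 4 were lower adjusted over the list alone. Clusters 28 and 54 of this class, led by the granule gene Ngp, held 32 of 2398 and 306 of 3875 placebo cells and 81 of 2435 and 64 of 3047 tamoxifen cells. Without them the list was called in the other direction, with a median log2 fold change of 0.23, a mean of 0.01 and an adjusted p of 0.0430 by camera, and 0 members passed adjusted over the list alone. Lists without a cluster of their class were tested at the preset correlation only, here and in the macrophage-like classes. The log2 fold change of Camp went from -1.42 to -0.93, that of Chil3 from -2.42 to a smaller one still below 0, and neither passed. The mitochondrially encoded genes were higher there, with a median log2 fold change of 0.36 over 13 genes, an adjusted p of 1.27e-09 by camera and adjusted p = 0.804 with an estimated correlation, and 0 were higher adjusted over the list alone.

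In B cell-like cells the proliferation list was higher, with an adjusted p of 1.07e-12 by camera and adjusted p = 0.778 with an estimated correlation. Mcm6, a DNA replication gene, was at 15.6 ± 5.97 and 37.0 ± 9.68 CPM (SD, n = 2), none of 21 passed over all genes, and 5 were higher adjusted over the list alone. Ribosomal protein genes were higher there by a median log2 fold change of 0.19, with an adjusted p of 3.69e-08 by camera, adjusted p = 0.778 with an estimated correlation and 0 of 92 higher adjusted over the list alone. The ribosomal list was called higher in 6 of the 8 classes.

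In CD8 T cell-like cells the cytotoxic effector list was higher, with an adjusted p of 6.25e-07 by camera and adjusted p = 0.651 with an estimated correlation. Ccl4, a chemokine gene, was at 24.2 ± 25.9 and 114 ± 56.5 CPM and granzyme B, Gzmb, at 25.7 ± 5.39 and 52.4 ± 1.69 CPM (SD, n = 2), none of 15 passed over all genes, and 2 were higher adjusted over the list alone. In alveolar fibroblast-like cells the heat shock list was higher, with an adjusted p of 3.42e-08 by camera and adjusted p = 0.818 with an estimated correlation. The chaperone gene Hspd1 was at 114 ± 7.04 and 167 ± 22.9 CPM (SD, n = 2), none of 15 passed over all genes, and 0 were higher adjusted over the list alone.

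Haemoglobin genes, which belong to red cells, moved in both directions as a list of 5. The list was lower in CD8 T cell, neutrophil and interstitial macrophage-like cells, with median log2 fold changes of -1.37, -1.22 and -0.69, and adjusted p of 1.12e-33, 1.27e-09 and 0.000500 by camera. It was higher in alveolar macrophage, CD4 T cell and alveolar fibroblast-like cells, with medians of 1.58, 0.47 and 0.14, and adjusted p of 6.23e-17, 8.71e-05 and 0.0492 by camera. These calls had adjusted p = 0.558, 0.804 and 0.705 and adjusted p = 0.585, 0.625 and 0.818 with an estimated correlation. Adjusted over the list alone, 5, 2 and 1 genes were lower and 5, 0 and 0 were higher. Without cluster 73 the median in alveolar macrophage-like cells was 0.66, with an adjusted p of 0.00136 by camera and 0 genes higher adjusted over the list alone. The naming rule left some haemoglobin-rich clusters unnamed. Their best or second scores were for neutrophil (33 and 56), CD4 T cell (67), alveolar macrophage (74) and B cell (75). Cluster 33 held 88 and 51 placebo cells and 29 and 151 tamoxifen cells. No such cluster was left out for CD8 T cells or interstitial macrophages, and what this did to the list was not tested.

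Tamoxifen binds oestrogen receptors, so Esr1, Pgr and Greb1 were read in every main class. Esr1 had 0 to 10 UMIs per mouse in each class, Pgr had 0 throughout and Greb1 had 0 to 11. All 3 genes stayed below the count filter, so a difference was not detectable at this depth. The oestrogen response list was called in 1 of the 8 classes, CD8 T cell-like cells, where it was higher by a median log2 fold change of 0.23 over 11 genes, with an adjusted p of 0.0208 by camera and adjusted p = 0.651 with an estimated correlation. None of its members passed, 0 were higher adjusted over the list alone, and Igfbp4 was at 104 ± 6.05 and 144 ± 36.7 CPM (SD, n = 2). In alveolar fibroblast-like cells the test pointed up with a median of -0.06, in neutrophil-like cells down with a median of 0.07, and in alveolar macrophage-like cells up with a mean of -0.08, none of them called.

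Outside the main classes 79 genes were called, in 5 of 13 classes. These calls were not run under the alternatives, apart from the mesothelial-like class without clusters 65 and 72. In club or secretory-like cells Bpifa1, a secreted airway protein gene, rose from 198 ± 9.38 to 4737 ± 586 CPM (SD, n = 2), a log2 fold change of 4.57 ± 0.49 (SE) with an edgeR adjusted p of 0.000119. That class held 34 and 62 placebo cells and 48 and 111 tamoxifen cells. In mesothelial-like cells 43 genes rose, among them the B cell chemokine gene Cxcl13, from 7.85 ± 7.10 to 893 ± 530 CPM, and fibronectin, Fn1, from 10.9 ± 4.79 to 798 ± 546 CPM (SD, n = 2). The macrophage genes C1qa, C1qb and C1qc were among the 43. Clusters 65 and 72 belonged to this class and held 16 of 124 placebo cells and 148 of 368 tamoxifen cells. Without them no gene was called by edgeR. Of 8696 tested genes, 372 then had an unadjusted p under 0.05, fewer than the 5% that chance gives.

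In natural killer-like cells 26 genes fell, among them the neutrophil genes G0s2, from 748 ± 36.2 to 91.2 ± 97.5 CPM, and Retnlg, from 448 ± 46.3 to 69.1 ± 50.4 CPM (SD, n = 2). The MHC class II genes H2-Ab1, H2-Aa and Cd74 were also among the 26, at 2.31%, 2.68% and 2.75% of their level in type 1 dendritic-like cells. The class held 98 and 39 placebo cells and 49 and 43 tamoxifen cells. In general capillary endothelial-like cells Irf8, Cd83, Plbd1 and Bcl2a1b rose, with Irf8, a transcription factor of myeloid and B cells, going from 6.32 ± 0.218 to 84.1 ± 21.5 CPM (SD, n = 2). These genes lay at 1.08% to 4.45% of their level in their highest class, which was a dendritic one for each. In type 1 dendritic-like cells Retnlg, C1qa, Nrgn, Cxcl1 and C1qb rose, with Retnlg going from 13.2 ± 11.0 to 115 ± 38.1 CPM (SD, n = 2). Each lay under 1% of its level in its highest class, with Retnlg at 0.874% of neutrophil-like cells, C1qa, C1qb and Cxcl1 at 0.371%, 0.424% and 0.940% of interstitial macrophage-like cells and Nrgn at 0.0515% of platelet or megakaryocyte-like cells.

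No cluster took the name of the mammary tumour markers. No gene of the matrices was named for the transgene, so tumour cells were looked for by mammary genes alone, which normal mammary cells also express. Cells with UMIs of at least 3 mammary genes numbered 0 of 7433 and 3 of 6651 in the placebo mice and 1 of 6804 and 0 of 7420 in the tamoxifen mice. In placebo 2 that was 0.0451% (95% Clopper-Pearson interval 0.00930 to 0.132%) and in tamoxifen 1 0.0147% (0.000372 to 0.0819%), and by a limit of 3 counts a count of 0 allows up to 0.0404% in placebo 1 and in tamoxifen 2. Csn3, a milk casein gene, had 482 UMIs in 11 cells of placebo 2, which was 0.165% of its cells (0.0826 to 0.296%), and 2 UMIs in 2 cells of tamoxifen 1.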

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

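The test on haemoglobin genes was chosen after the result was seen, as were the 56 tests of differences between classes, and the tests on mesothelial and natural killer-like cells were set before their values were seen but after the names of the called genes were.

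Tamoxifen effects of called genes differed between the class of the call and others of the 7 other main classes, by an edgeR test of the difference with the mouse as a block. The Hbb-bs effect in CD8 T cell-like cells differed from that in 5 classes, that of Hba-a1 from 4, that of Hbb-bt from 3, that of Ier3 from 6 and that of Trbv20 from 3. The Cd74 effect in CD4 T cell-like cells differed from that in 6 classes and the Marco effect in interstitial macrophage-like cells from that in 1. The genes were tested because they had been called in the first class, which favours a difference.

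Lower haemoglobin in CD8 T cell-like cells was weighed against free red cell RNA that reaches every class of a mouse alike. The Hbb-bs log2 fold change was lower in CD8 than in CD4 T cell-like cells of the same mice. The difference was -1.79 ± 0.11 (SE), and against neutrophil-like cells it was 0.03 ± 0.35 (SE). Against non-classical monocyte, interstitial macrophage and B cell-like cells it was -1.24 ± 0.39, -0.70 ± 0.22 and -1.06 ± 0.65 (SE). Against alveolar macrophage and alveolar fibroblast-like cells it was -2.93 ± 0.25 and -3.16 ± 0.77 (SE). The naming rule had left cluster 67, haemoglobin-rich with CD4 T cell as its second score, out of the CD4 class. It held 50 and 1 placebo cells and 10 and 26 tamoxifen cells. The contrast with CD4 T cell-like cells therefore cannot decide on an equal background. Those with non-classical monocyte and interstitial macrophage-like cells, which had no such cluster left out, passed the edgeR test (adjusted p 0.00787 and 0.0121). Those with neutrophil and B cell-like cells did not pass. Hbb-bs was chosen for its call in CD8 T cell-like cells, which favours a difference, so an equal background stays open. Red cells that adhered to some of the cells or shared their droplets, and an effect of tamoxifen, were not tested and stay open.

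For 42 of the 43 genes higher in mesothelial-like cells a fold could be fitted without clusters 65 and 72, with no count filter, and their median log2 fold change was 3.53 with these clusters and 1.40 without them. Of the 43 genes, 83.7% had a mesothelial mean under 20% of that in their highest class, 0 were highest in mesothelial-like cells, and 15 were highest in macrophage and 11 in fibroblast classes. Those above 20% included Cxcl13 at 47.1% and Fn1 at 37.9% of interstitial macrophage-like cells. Lgals1 was at 77.0% of natural killer-like and Twist1 at 82.2% of adventitial fibroblast-like cells. A changed make-up of the class could give the lower median and the 83.7%, through its clusters or through RNA or cells of other classes. The tests do not say which, and the share under 20% was not computed for all genes tested in the class. The median without the clusters was still above 0 but was not tested against it. The genes had been chosen as higher with tamoxifen in a class that included the same cells, which favours a median above 0. A response of mesothelial cells to tamoxifen was therefore neither shown nor excluded.

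Of the 26 genes lower in natural killer-like cells, 96.2% had a natural killer mean under 20% of that in their highest class, and 15 were highest in neutrophil-like and 4 in type 1 dendritic-like cells. RNA or cells of other classes among the natural killer-like cells of the placebo mice could give this. The share was not computed for all 3436 genes tested in the class, so it does not separate the explanations. A change within natural killer cells was not tested and stays open.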

How the results depend on the processing

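The classes without cluster 47, 73, 28 and 54 or 65 and 72, the total without erythroid cells and mixed clusters, and the replicate block with crossed numbers were chosen after seeing the data. No share was called under any alternative run, and alternatives for single shares were followed, after their values were seen, only in the main classes and those whose groups lay apart. Of the values of single genes and shares under alternatives, 899 kept their direction and side of the threshold, 99 passed it, 19 lost it and 11 reversed. All 19 losses fell on the 8 called genes of the main classes, and each of these lost its call under some alternative. Most of the values belonged to genes and shares that were not called, where keeping the side meant staying uncalled. A gene filtered out under an alternative has no value there. Genes under the count filter and fine differences in classes of few cells are beyond this depth.

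Classes are given in the order neutrophil, alveolar macrophage, CD4 T, alveolar fibroblast, non-classical monocyte, B, interstitial macrophage and CD8 T, whose called genes numbered 0, 0, 1, 0, 0, 1, 1 and 5. With no count filter they numbered 47, 55, 41, 65, 20, 106, 0 and 43, and with the replicate block 1, 28, 2, 1, 5, 107, 35 and 26. Leaving out each mouse gave 0 to 157, 0 to 42, 2 to 82, 0 to 97, 9 to 40, 1 to 26, 11 to 75 and 16 to 86. The highest came without placebo 1 in neutrophil, alveolar macrophage, CD4 T, alveolar fibroblast, B and CD8 T, without placebo 2 in non-classical monocyte and without tamoxifen 2 in interstitial macrophage. The mouse left alone in its group is there assumed to vary like the others. DESeq2 called 1 gene in neutrophil, 3 in B, 8 in interstitial macrophage and 3 in CD8 T. Cells assigned singly gave 0 in CD4 T, 0 in B and 14 in CD8 T. Equal cells gave 4 in alveolar macrophage, 0 in CD4 T, 2 in B, 2 in interstitial macrophage and 0 in CD8 T. The stricter cell filter gave 6 in alveolar macrophage, and doublets kept gave 2 in non-classical monocyte. Leaving out genes under 5% of their highest class gave 2 in CD4 T, 4 in B, 4 in interstitial macrophage and 1 in CD8 T. Interstitial macrophage had 0 without cluster 47, and mesothelial had 0 in place of 43 without clusters 65 and 72. The cause was not tested.

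List calls numbered 5, 10, 8, 8, 4, 7, 9 and 6, and 0 in each class with an estimated correlation and with fry. Leaving out each mouse gave 7 to 14, 7 to 12, 7 to 9, 7 to 16, 4 to 13, 3 to 12, 8 to 18 and 4 to 9. The highest came without placebo 1 in neutrophil and alveolar fibroblast, without placebo 2 in B and interstitial macrophage and without either in non-classical monocyte, and the lowest in B without placebo 1. With doublets kept non-classical monocyte had 8, with no count filter interstitial macrophage had 15, and without genes under 5% of their highest class CD4 T had 2 and CD8 T had 2. The cause was not tested.

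The labels pair no mice. Deviations of same-numbered mice correlated across genes, which are not independent, between -0.168 in neutrophil and 0.175 in alveolar fibroblast, and with 2 mice per group no pairing can be read from this. The block with crossed numbers gave 10 genes and 9 lists in neutrophil.

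On the log2 scale and with cells assigned singly, Hbb-bt and Il1b in alveolar macrophage reversed to -0.16 and -0.65 and Cd74 in alveolar fibroblast to -0.76. None of them had been called. Leaving out each mouse took Chil3 in non-classical monocyte from -1.50 to 0.61, and shares from -0.60 to 0.25 in neutrophil, -0.33 to 1.02 in CD4 T, -0.26 to 0.98 in CD8 T, -0.34 to 2.04 in B and -0.0624 to 0.43 in non-classical monocyte. The reversals came without placebo 2 for all of these but B, and without tamoxifen 1 for B, CD4 T and CD8 T. The cause was not tested.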

Other observations

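Cluster 47, led by Retnla, Fcna, Prg4 and Alox15, also had C1qa, C1qb, C1qc and Cxcl13 among its 10 leading genes. It held 40 and 9 placebo cells and 76 and 69 tamoxifen cells, with a median of 12897.5 UMIs per cell. Its share was not tested apart from its class, and it was singled out after its cells per mouse had been seen. In non-classical monocyte-like cells Retnla was at 90.2 ± 93.8 and 4.32 ± 6.11 CPM (SD, n = 2), and its edgeR adjusted p of 0.0805 did not pass.

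Cluster 66 was led by the heart muscle genes Myl4, Tnnt2, Tnni3, Sln and Myh6 and stayed unnamed. It made up 0.300 ± 0.214% of placebo cells and 0.410 ± 0.373% of tamoxifen cells (SD, n = 2), with an edgeR adjusted p of 0.939.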
